A study of Mus musculus with 28 samples.

How the data were processed

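Nuclear RNA was sequenced from longitudinal muscle and myenteric plexus preparations of mouse small intestine and colon, 5 weeks after an adeno-associated virus carrying a fluorescent nuclear envelope protein under a CaMKII promoter had been given. Per the labels, sorting gave a fluorescent fraction and a non-fluorescent fraction from germ-free (GF) and specific pathogen-free (SPF) animals. Libraries were made with an amplification kit and 8 PCR cycles and read as 75 bp single ends.

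The authors deposited 1 table of expected counts per gene, with 51912 genes and 28 libraries. Expected counts are estimates that share reads between genes they match, and 7.478% of the deposited values were not whole. Per the submitters' processing notes, RSEM 1.3.0, STAR 2.5.2, DESeq2 1.10.1 and the GRCm38 genome were used, with no role or order given for them. Whether the counting was strand-specific is not given in the sources used here, so reads of overlapping genes on opposite strands may not have been separated. Values were rounded to whole counts. Gene identifiers were matched to GENCODE M21 for 51719 genes, and the 193 unmatched genes held 0.1022% of the counts and were kept in the tests.

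Library totals ranged from 2394481 to 7321875 counts. A floor of 3 counts per library, the upper limit that a count of 0 allows, stood between 0.41 and 1.25 CPM, counts scaled to the library total, depending on the library. The libraries carried no molecular identifiers, so floors cover counting error only. Folds against a group whose libraries all held 0 counts were computed against the highest floor per library of that group and are given as lower bounds. All other levels are CPM scaled by the library total. Other folds are ratios of such mean levels, while log2 fold changes come from the fits described below, which also apply TMM scaling, so these can differ.

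Groups followed the labels: 8 groups from 2 gut segments, 2 sorted fractions and 2 microbiota states, with 3 GF or 4 SPF libraries in each. The labels do not tie the libraries to separate animals, so the p-values measure the spread between these libraries, which may be technical in part. Identical or near-identical libraries were looked for among the 36 pairs within groups, and none were identical.

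The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, a low-count filter by group and robust dispersion. Comparisons between sorted fractions, and interactions that cross them, were fitted on all 28 libraries with a mean per group (20964 genes tested). Comparisons within a fraction were fitted on its 14 libraries (17298 genes for the neuronal and 18267 for the non-neuronal fraction). Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison, and all tests were two-sided. Standard errors (SE) of log2 fold changes were the absolute log2 fold change over the square root of F. Ahr was also compared between groups with exact two-sided permutation tests on the difference of mean log2(CPM + 1).

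The 39 gene lists, 16 of them cell type markers, were fixed before the data were examined. In each comparison 33 or 38 of the lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The p-values were adjusted over the lists of that comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Alternatives were camera with an estimated correlation and fry. The list of sex-linked genes was used only to look for differences between libraries within groups, and its levels are not reported.

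Genes named in the text followed a rule fixed at the same time. In each comparison they were the 10 called genes with the largest rise and the 10 with the largest fall that had a mean of at least 5 CPM in the higher group, no overlap between the libraries of the 2 groups and a named symbol. For interactions overlap was not considered. Where fewer than 5 genes qualified, the 5 of lowest p were taken and given as values. Members of the fixed lists serve as examples. Of the genes that met this rule, 2 are not reported here.

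Alternatives to the main processing were size factors of the relative log type, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter at a mean of 2 CPM, only the compared groups in the fit, all 28 libraries in the fit, a replicate block and leaving out each library in turn. Added after the data were seen were a fit with SPF replicates 1 and 2 only, a term for the SPF libraries that Xist set apart, and a replicate block for 2 of the interactions.

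The edgeR steps were tested on simulated data made from the fitted dispersions of 4 comparisons, with 50 genes changed at each fold size. For fractions in the SPF colon, 2% of genes changed 2-fold, 30% of those changed 8-fold and 40% of those changed 16-fold were called. Between segments in SPF neuronal libraries the shares were 2%, 50% and 58%, and between SPF and GF colonic neuronal libraries 4%, 36% and 62%. Between SPF and GF colonic non-neuronal libraries they were 0%, 28% and 36%. Wrong calls numbered 0, 6, 3 and 7 in these 4 simulations.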

Results

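The study compared nuclear RNA of enteric neurons with that of the surrounding cells of the gut muscle wall, in 2 gut segments and with or without a microbiota. Fluorescent nuclei are called neuronal here and non-fluorescent nuclei non-neuronal, after the sort. The 28 libraries formed 8 groups, with 4 SPF or 3 GF libraries for each fraction of the colon and of the small intestine. Library totals ran from 2394481 to 7321875 counts, and 10286 to 16472 genes per library reached 10 counts. Across genes, the log levels of libraries within a group correlated at r 0.685 to 0.901, although genes are not independent replicates. Mitochondrially encoded genes took 0.42% to 0.60% of counts in SPF and 0.87% to 1.06% in GF colonic neuronal libraries. They took 2.75% to 6.82% in small intestinal neuronal libraries and 3.49% to 10.8% in colonic non-neuronal libraries. In small intestinal non-neuronal libraries they took 11.1% to 12.9% with and 13.4% to 35.6% without a microbiota.

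The comparison of the sorted fractions asked which transcripts mark the neuronal nuclei. In the SPF colon, neuronal libraries held more RNA of the single genes Prph, Penk, Gal and Uchl1. They held less RNA of smooth muscle and fibroblast markers, and epithelial markers ran from -9.42 to -4.43 in log2 fold change. Prph, which encodes the intermediate filament peripherin, averaged 599 CPM in 4 neuronal and 87.2 CPM in 4 non-neuronal libraries (log2 fold change 2.74, SE 0.53, edgeR adjusted p = 6.42e-04). Penk, the precursor of enkephalins, was 20.6-fold higher, Gal (galanin) 20.4-fold higher and Uchl1, a neuronal ubiquitin hydrolase, 15.3-fold higher. Smtn, a smooth muscle actin-binding protein, was 78.6-fold lower in neuronal libraries (1043 against 13.3 CPM), and Myh11, the smooth muscle myosin heavy chain, was 22.0-fold lower. In the SPF small intestine, Prph averaged 375 against 2.50 CPM, Elavl4 was 37.0-fold higher, Vip, an inhibitory neuropeptide, 45.2-fold higher and Penk 58.1-fold higher.

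Of the 12 pan-enteric neuron markers, 4 were higher in SPF colonic neuronal libraries (6 adjusted over the list alone), with a median log2 fold change of 1.97 (camera adjusted p = 5.59e-07). That call was lost, with adjusted p = 0.0538 with an estimated correlation. In the SPF small intestine 11 of the 12 rose (11 adjusted over the list alone), with a median of 5.03 (camera adjusted p = 5.27e-15). GF libraries gave medians of 2.401 in the colon (3 higher, 6 adjusted over the list alone, camera adjusted p = 3.13e-07) and 5.18 in the small intestine (9 higher, 10 adjusted over the list alone, camera adjusted p = 1.07e-11). All 10 smooth muscle markers and all 9 fibroblast markers were lower in neuronal libraries in each of the 4 fraction comparisons, also adjusted over each list alone, and the smooth muscle medians were -3.37, -4.06, -4.45 and -4.30 in SPF colon, SPF small intestine, GF colon and GF small intestine. Cholesterol synthesis genes were higher in small intestinal neuronal libraries, with 8 of 12 called in SPF (10 adjusted over the list alone, median 2.53, camera adjusted p = 1.54e-07) and 6 of 12 in GF (8 adjusted over the list alone, median 2.90, camera adjusted p = 5.65e-07); Fdps, which makes farnesyl diphosphate, was 46.0-fold higher in SPF. Mitochondrially encoded genes fell in neuronal libraries with medians of -3.19, -1.72, -2.68 and -3.38 in the same order (9, 7, 9 and 9 of 13 called, and 11, 8, 11 and 10 adjusted over the list alone), and in the SPF small intestine that call was lost, with adjusted p = 0.111 with an estimated correlation.

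Interstitial cell of Cajal markers, genes of the pacemaker cells of gut muscle, did not follow the smooth muscle and fibroblast lists in the SPF small intestine. In the SPF colon 4 of these 5 markers were lower in neuronal libraries (5 adjusted over the list alone), with a median log2 fold change of -6.64 (camera adjusted p = 3.52e-07), and Ano1, a calcium-activated chloride channel of these cells, was 217-fold lower. In the GF colon 3 fell (4 adjusted over the list alone), with a median of -5.48, or -4.02 with genes absent from the lower group at their bound (camera adjusted p = 5.70e-06). In the SPF small intestine the median was 0.47 (camera adjusted p = 0.936), and Ano1 stood at 247 CPM in neuronal and 168 CPM in non-neuronal libraries (log2 fold change 0.44, SE 0.61, or -0.83 without SPF small intestinal neuronal replicate 1). The list members ran from -5.14 to 3.79 there. In the GF small intestine the median was -1.80 (camera adjusted p = 0.0586).

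Across all genes, edgeR called 2270 genes between the fractions of the SPF colon (686 higher and 1584 lower in neuronal libraries) and 3161 in the SPF small intestine (1905 higher, 1256 lower). It called 1500 in the GF colon (460 higher, 1040 lower) and 2291 in the GF small intestine (1173 higher, 1118 lower). Most genes of largest change had no counts in 1 of the fractions. In the SPF colon, Pcdha2 was at least 19.3-fold and the potassium channel gene Kcnh4 at least 19.2-fold higher in neuronal libraries, while the endothelial gene Ecscr was at least 142-fold and the mucus cell stress sensor Ern2 at least 117-fold lower. In the SPF small intestine, the ephrin receptor gene Epha8 was at least 107-fold and Phox2a, a regulator of autonomic neurons, at least 34.7-fold higher, while the secreted protease gene Htra3 was at least 23.3-fold lower. In the GF colon, the relaxin family receptor gene Rxfp3 was at least 27.8-fold higher, and the lymphatic chemokine gene Ccl21a and the matrix gene Ccn1 were at least 285-fold and 156-fold lower. In the GF small intestine, the cation channel gene Trpc7 and Phox2a were at least 87.2-fold and 66.1-fold higher, while mt-Co3 stood at 0.127 CPM (2 counts) in neuronal against 479 CPM in non-neuronal libraries and Adh6a was at least 61.2-fold lower. The protocadherin alpha genes share exons and Ccl21a has near-identical copies. Phox2a overlaps Inppl1 on the other strand and mt-Co3 overlaps mt-Atp6 on the same strand. Reads of all these genes may therefore be shared. In the GF colon, 773, 880 and 948 genes were called without neuronal replicates 2, 1 and 3, and 892 and 931 without non-neuronal replicates 1 and 3. Without GF small intestinal neuronal replicate 1, 1454 were called in the GF small intestine.

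Neurons of the colon and the small intestine were compared to find what sets them apart by segment. In SPF neuronal libraries, colonic neurons held more of the membrane collagen gene Col25a1 (ENSMUSG00000058897, chromosome 3, 130131501 to 130599877, GRCm38), at 236 ± 94.0 CPM (mean ± SD) in 4 colonic against 11.5 ± 5.72 CPM in 4 small intestinal libraries, 20.6-fold (log2 fold change 4.19, SE 0.45, edgeR adjusted p = 4.99e-06). Ano5, of the anoctamin family, averaged 155.5 ± 26.8 against 11.1 ± 5.02 CPM, and the POU-domain transcription factor gene Pou3f3 averaged 127 against 0.382 CPM. Penk was 5.46-fold and Tac1, the precursor of substance P, 3.63-fold higher in the colon, and Ntrk2, the receptor of brain-derived neurotrophic factor, 4.14-fold higher. Ahr, which encodes the ligand-activated aryl hydrocarbon receptor, was 9.56-fold higher, at 134 ± 44.5 against 13.98 ± 12.5 CPM (log2 fold change 3.14, SE 0.65, edgeR adjusted p = 0.0147). Lower in the colon were Ano1 (ENSMUSG00000031075, chromosome 7, 144588549 to 144751974), at 0.579 against 247 ± 288 CPM, and the orphan receptor gene Gpr20, at least 50.2-fold.

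The interstitial cell list was the only cell type list called by camera in SPF colonic relative to small intestinal neuronal libraries: 3 of its 5 genes were called (4 adjusted over the list alone), with a lower level in the colon and a median log2 fold change of -8.80, or -5.06 with absent genes at their bound (camera adjusted p = 1.56e-14). Kit, the receptor tyrosine kinase of these cells, stood at 8.28 ± 9.60 against 243 ± 230 CPM (log2 fold change -5.06, SE 1.63, adjusted p = 0.267). Ano1 lay between 24.2 and 679 CPM in the 7 small intestinal neuronal libraries of both microbiota states, with the highest value in SPF replicate 1, and between 0 and 1.60 CPM in the 7 colonic ones. Mitochondrially encoded genes were lower in the colon, with 8 of 12 called (9 adjusted over the list alone, median -3.16, camera adjusted p = 7.13e-27). Hox genes of paralogue groups 3 to 8 had a median of -1.69 with 0 of 14 called (5 adjusted over the list alone, camera adjusted p = 3.04e-04), a call that was lost, with adjusted p = 0.118 with an estimated correlation. The pan-enteric neuron list had a median of 0.20 (camera adjusted p = 0.722). Among transmitter genes, Nos1, the neuronal nitric oxide synthase, stood at 1676 against 971 CPM (log2 fold change 0.63, SE 0.20, adjusted p = 0.181), and the choline transporter gene Slc5a7 at 97.8 against 190 CPM (adjusted p = 0.135).

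edgeR called 113 genes in this comparison, 43 higher and 70 lower in the colon. The colonic genes of largest change also held Kctd16, at least 16.8-fold higher, Syt10, at 11.8 against 0.0546 CPM, Prr5 (14.1-fold), Wnk4 (8.98-fold), Iqcj (10.1-fold), and Pantr2, a noncoding gene beside Pou3f3, at 19.2 against 0.0628 CPM. The genes lower in the colon held Edn3, the ligand of the endothelin B receptor, at least 21.5-fold, Cdh9 at least 15.2-fold, Capn12 at least 11.2-fold, Adgrd1 278-fold, Osr1 112-fold and Prkcq, at 0.239 against 101.5 CPM. Capn12 overlaps Actn4 on the other strand. Leaving out SPF small intestinal neuronal replicates 4 and 3 gave 57 and 75 genes, and leaving out SPF colonic neuronal replicates 1, 2 and 3 gave 72, 67 and 72. With all 28 libraries in the fit Penk, Tac1 and Ahr were not called (adjusted p = 0.302, 0.535 and 0.171), and Ahr was not called without SPF colonic neuronal replicate 3 (adjusted p = 0.077) or SPF small intestinal neuronal replicate 3 (adjusted p = 0.0624).

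**Figure D1:**
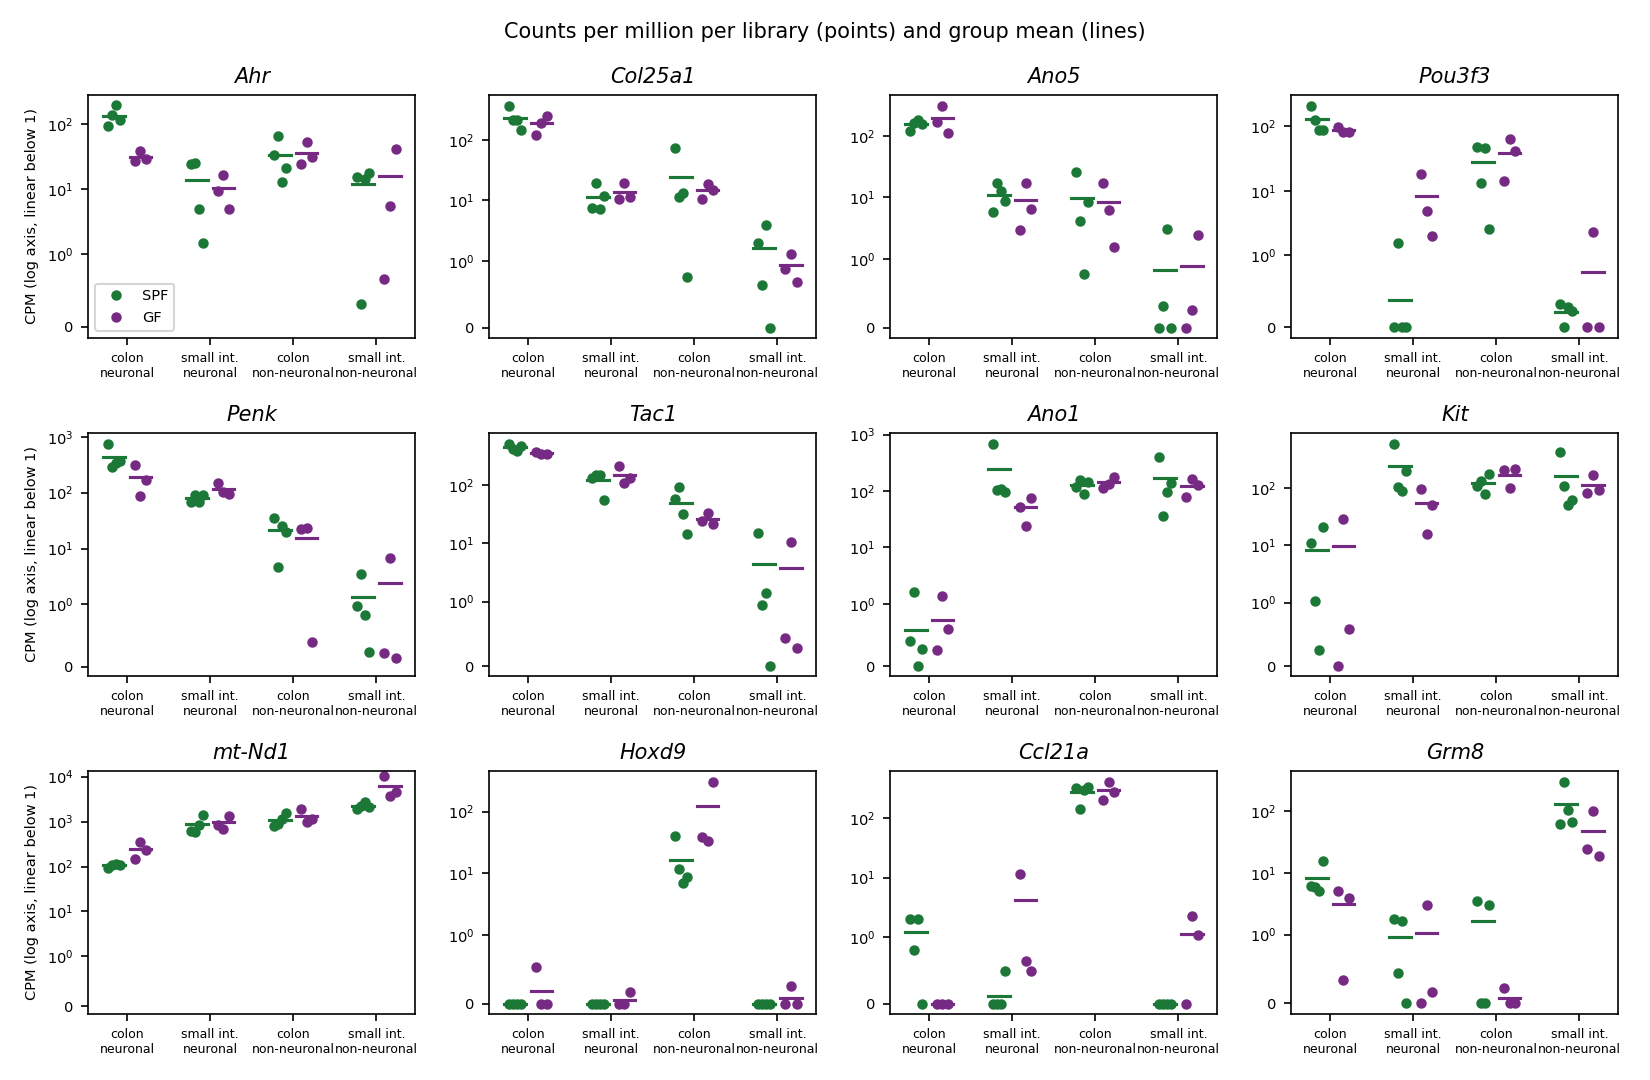
Levels in CPM of 12 genes in each of the 28 libraries (points) with group means (lines), SPF in green and GF in purple, on an axis that is logarithmic above 1 CPM and linear below it. Ahr sat between 91.3 and 194 CPM in the 4 SPF colonic neuronal libraries and between 26.6 and 38.4 CPM in the 3 GF ones, and Ano1 sat between 0 and 1.60 CPM in the 7 colonic neuronal libraries and between 24.2 and 679 CPM in the 7 small intestinal ones.

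In GF neuronal libraries the same question was asked of 3 colonic and 3 small intestinal libraries. Colonic neurons held more Pde1c, a calmodulin-dependent phosphodiesterase gene, at 566 ± 48.1 against 40.0 ± 26.4 CPM, 14.1-fold (log2 fold change 3.90, SE 0.41, edgeR adjusted p = 1.02e-05). Ano5 was 21.7-fold, Wnk4 15.3-fold and Col25a1 13.9-fold higher in the colon, and the serotonin receptor gene Htr2b 3.68-fold. Lower in the colon were Ano1 (69.7-fold), Prkcq (58.7-fold), the phosphodiesterase gene Pde4c (74.4-fold), Gpr20 (at least 18.7-fold) and Rasgef1b (at least 31.8-fold). Ahr stood at 31.4 ± 6.22 against 10.2 ± 5.68 CPM (log2 fold change 1.67, SE 0.72, adjusted p = 0.419).

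The interstitial cell list had a median of -5.80, or -3.68 with absent genes at their bound, with 2 of 5 genes lower (3 adjusted over the list alone, camera adjusted p = 6.02e-08), and that call was lost, with adjusted p = 0.106 with an estimated correlation. Mitochondrially encoded genes had a median of -2.49, with 3 of 12 lower (9 adjusted over the list alone, camera adjusted p = 4.06e-14) and adjusted p = 0.140 with an estimated correlation. edgeR called 52 genes, 23 higher and 29 lower in the colon, and 12 genes were higher and 16 lower in both SPF and GF (0.0572 and 0.117 expected for independent lists), with 0 opposite. Camera also called the smooth muscle list (median -0.73, 0 of 10 called, 3 lower adjusted over the list alone, camera adjusted p = 0.00855), a call that was lost, with adjusted p = 0.367 with an estimated correlation. Htr2b overlaps Psmd1 on the other strand. Without GF small intestinal neuronal replicates 1, 2 and 3, 27, 34 and 24 genes were called, and 34 without GF colonic neuronal replicate 2.

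In non-neuronal libraries of SPF animals, the genes higher in the colon than in the small intestine included posterior Hox genes and the lymphatic chemokine gene Ccl21a. Ccl21a averaged 265 ± 85.3 CPM in 4 colonic libraries and was absent from 4 small intestinal ones, at least 273-fold higher (edgeR adjusted p = 7.57e-08). The posterior patterning genes Hoxa13, Hoxa10 and Hoxd9 were at least 30.8-fold, 24.9-fold and 17.2-fold higher in the colon, and all 9 Hox genes of paralogue groups 9 to 13 were higher when adjusted over the list alone (4 over all genes), with a median log2 fold change of 6.49, or 4.97 with absent genes at their bound (camera adjusted p = 1.10e-10). Of the endothelial markers, Prox1, a regulator of lymphatic identity, was 43.5-fold and Emcn 139-fold higher, the only 2 of 9 called (2 adjusted over the list alone, median 2.01, camera adjusted p = 0.00121). Lower in the colon were the metabotropic glutamate receptor gene Grm8 (79.4-fold), the matrix gene Ltbp2 (98.2-fold), the diacylglycerol kinase gene Dgkb (15.9-fold), and the secretin receptor gene Sctr, at 0.108 against 65.4 CPM.

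Neuronal transcripts were also higher in these colonic non-neuronal libraries. Of the enteric neurotransmitter receptor genes, P2rx2 was 44.2-fold and Chrna3 13.6-fold higher, with 2 of 21 called (13 higher adjusted over the list alone, median 2.76, camera adjusted p = 6.98e-07). The pan-enteric neuron list had a median of 2.35, with 1 of 12 higher (4 adjusted over the list alone, camera adjusted p = 5.22e-08), and that call was lost, with adjusted p = 0.0996 with an estimated correlation. Smooth muscle markers had a median of -0.59, with 2 of 10 lower (5 adjusted over the list alone, camera adjusted p = 0.00166) and adjusted p = 0.271 with an estimated correlation; Mylk, the myosin light chain kinase gene, fell 1.99-fold. Mitochondrially encoded genes had a median of -1.95 (1 of 13 lower, 10 adjusted over the list alone, camera adjusted p = 5.66e-13; adjusted p = 0.0996 with an estimated correlation). edgeR called 199 genes, 102 higher and 97 lower in the colon. Leaving out SPF colonic non-neuronal replicates 1, 2 and 4 gave 122, 79 and 97 genes, and leaving out SPF small intestinal non-neuronal replicates 1, 2 and 3 gave 292, 104 and 122.

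In GF non-neuronal libraries Ccl21a and posterior Hox genes were again among the genes higher in the colon, and Sytl4 and Pnmal1 were at least 63.3-fold and 28.4-fold higher. Ccl21a was 256-fold higher in the 3 colonic libraries (edgeR adjusted p = 3.34e-05), Mmrn1, a lymphatic endothelial gene, 160-fold higher, and Hoxd9 stood at 124 ± 152 against 0.0848 CPM. Grm8 stood at 0.0756 against 47.0 CPM, and Hcn4, a pacemaker channel gene, was 61.5-fold, Sctr 49.8-fold, Il18r1 16.6-fold, the mesenchymal transcription factor gene Hand1 11.5-fold, Dgkb 10.0-fold and the Wnt agonist gene Rspo1 8.82-fold lower in the colon. TMM factors ran from 0.54 to 1.04 in GF small intestinal and from 1.14 to 1.36 in GF colonic non-neuronal libraries. After that scaling rises were smaller and falls larger than these CPM folds. The fitted log2 fold changes were 7.35 for Ccl21a, 6.76 for Mmrn1, -4.48 for Hand1, -4.08 for Dgkb and -4 for Rspo1. Hox genes of paralogue groups 9 to 13 had 3 of 9 higher (9 adjusted over the list alone), with a median of 7.46, or 4.33 with absent genes at their bound (camera adjusted p = 5.93e-12). The endothelial list had a median of 2.07 with 0 of 9 called, also adjusted over the list alone (camera adjusted p = 2.41e-04). Smooth muscle markers had 4 of 10 lower (5 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 4.36e-06) and adjusted p = 0.158 with an estimated correlation. Mitochondrially encoded genes had 8 of 13 lower (11 adjusted over the list alone, median -3.17, camera adjusted p = 3.38e-24). edgeR called 130 genes, 40 higher and 90 lower in the colon, and 21 genes were higher and 41 lower in both SPF and GF (0.223 and 0.478 expected for independent lists), with 0 opposite. Leaving out GF colonic non-neuronal replicates 1, 2 and 3 gave 44, 48 and 47 genes, and leaving out GF small intestinal non-neuronal replicates 1 and 3 gave 52 and 74. Dgkb overlaps a pseudogene and a noncoding antisense gene.

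**Figure D2:**
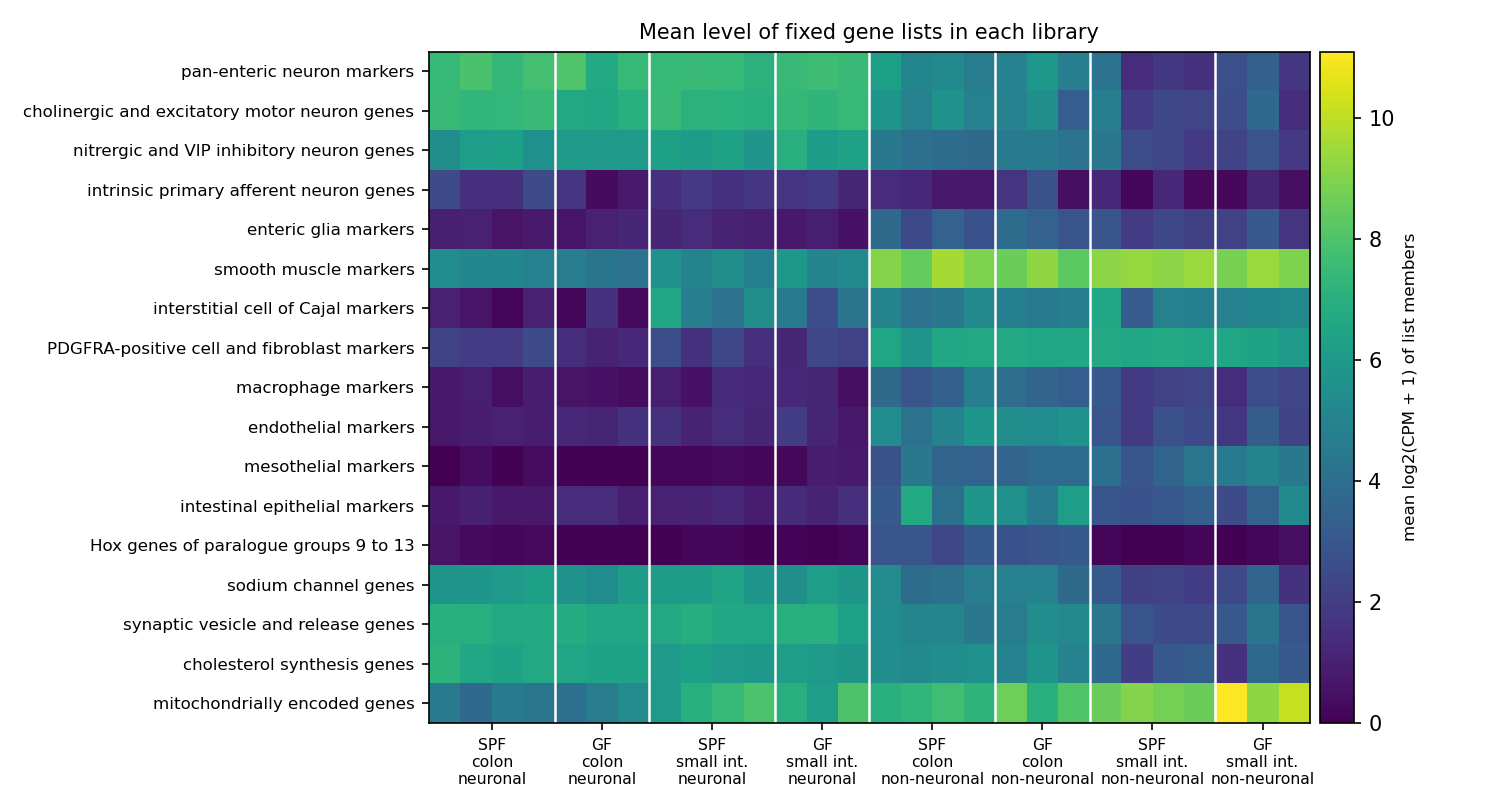
Mean log2(CPM + 1) of the members of fixed gene lists, named on the vertical axis, in each of the 28 libraries, which are grouped along the horizontal axis and separated by white lines, with the colour scale at the right. The pan-enteric neuron level of SPF small intestinal non-neuronal replicate 1 was 4.22, and the other 3 libraries of its group had at most 1.80.

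The comparison of SPF with GF animals asked which genes respond to the microbiota. In colonic neurons, Ahr (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038, GRCm38) was 4.26-fold higher on average in 4 SPF than in 3 GF libraries, at 134 ± 44.5 against 31.4 ± 6.22 CPM. Every SPF library (91.3 to 194 CPM) lay above every GF library (26.6 to 38.4 CPM). The log2 fold change was 1.96 with an SE of 0.69, and it did not pass over all genes (edgeR adjusted p = 0.411) but passed adjusted over the list alone, that of the receptor and its partners (edgeR adjusted p = 0.041). An exact two-sided permutation test gave p = 0.0571, the smallest that 4 against 3 libraries allow, and 0.228 after adjustment over 12 Ahr comparisons. The same exact permutation test between SPF colonic and small intestinal neurons gave p = 0.0286, also the smallest possible, and 0.172 after adjustment. The list of 3 AHR target genes had a median of 0.75 (camera adjusted p = 0.708).

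Elsewhere Ahr levels overlapped between SPF and GF. Ahr stood at 13.98 ± 12.5 against 10.2 ± 5.68 CPM in small intestinal neurons, at 32.9 ± 22.8 against 35.9 ± 15.1 CPM in colonic non-neuronal libraries and at 11.9 ± 7.84 against 15.7 ± 21.9 CPM in small intestinal non-neuronal libraries. In SPF animals Ahr was 4.07-fold higher in colonic neuronal than non-neuronal libraries (log2 fold change 1.97, SE 0.89, edgeR adjusted p = 0.151). The SPF to GF change of Ahr was not shown to differ between colonic and small intestinal neurons (difference 1.47, SE 0.93, edgeR adjusted p = 0.839) or between colonic neuronal and non-neuronal nuclei (difference 2.02, SE 1.33, edgeR adjusted p = 0.876).

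Among other genes of colonic neurons, edgeR called 0 between SPF and GF, with 1599 at an unadjusted p below 0.05. Of the 35 splits of the 7 libraries into 4 and 3, 12 gave at least 1599 such genes, the real one included, and the highest other gave 1915. DESeq2 called 138 and limma-voom 1. The genes of lowest p were Cited2, at 21.1 against 182 ± 232 CPM in SPF and GF, Stum, at 287 ± 260 against 47.6 CPM, Mxra8, at 15.7 against 151 ± 193 CPM, the Wnt target gene Lgr5, at 0.412 against 31.3 ± 24.9 CPM, and Akr1b3, at 9.56 against 53.0 CPM, with adjusted p from 0.287 to 0.388. The intrinsic primary afferent neuron list had a median of 2.59 with 0 of 5 called (2 adjusted over the list alone, camera adjusted p = 0.0191), and that call was lost, with adjusted p = 0.492 with an estimated correlation. Its members Cbln2 and Nmu were higher in SPF, by a log2 fold change of 4.91 (SE 1.80) and, with no GF counts, at least 6.10-fold, and Slc18a3, the vesicular acetylcholine transporter gene, had a log2 fold change of 3.07 (SE 0.75). Mitochondrially encoded genes had a median of -0.68 (0 called, 1 adjusted over the list alone, camera adjusted p = 0.0381; adjusted p = 0.636 with an estimated correlation). Leaving out GF colonic neuronal replicate 3 gave 5 genes.

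In small intestinal neurons edgeR called 0 genes (414 at an unadjusted p below 0.05, DESeq2 10, limma-voom 0), and lowest in p were Pou3f3, at 0.382 against 8.37 CPM in SPF and GF, and Rnf182, Gpat3, Ano1 and Glrx5. The interstitial cell list had a median of 2.25 with 0 called (1 adjusted over the list alone, Ano1 with 2.28, SE 0.70; camera adjusted p = 0.0036), and that call was lost, with adjusted p = 0.772 with an estimated correlation. Leaving out SPF small intestinal neuronal replicate 2 gave 1 gene. In colonic non-neuronal libraries edgeR called 0 genes (445 at an unadjusted p below 0.05, DESeq2 5, limma-voom 0) and camera called 0 of 38 lists. Pcp2, Tsc22d2, Arl5b, Slc36a2 and Slc47a1 had the lowest p there, all with adjusted p = 1.

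In small intestinal non-neuronal libraries 1 gene passed: Lats2, a kinase of the Hippo pathway, was 9.55-fold lower in SPF, at 15.9 ± 7.34 against 152 ± 55.9 CPM (log2 fold change -3.58, SE 0.60, edgeR adjusted p = 0.0368). This call rested on every SPF library and on GF replicate 3, since without any 1 of these its adjusted p lay between 0.0851 and 0.253. It was also lost with limma-voom, with only the compared groups in the fit, with a replicate block, with SPF replicates 1 and 2 only and with a term for the libraries that Xist set apart (adjusted p from 0.156 to 0.524). At an unadjusted p below 0.05 stood 1987 genes, and 14 of the 35 splits of these libraries gave at least as many, the real one included, with 2586 in the highest other. DESeq2 called 374 and limma-voom 0. Immediate early genes had a median log2 fold change of -1.02 with 0 of 11 called (4 lower adjusted over the list alone, camera adjusted p = 5.93e-04; adjusted p = 0.79 with an estimated correlation): Fosb stood at 3.58 against 43.7 CPM, Ier2 at 1.41 against 27.98 CPM, Arc at 0.0809 against 19.3 CPM and Atf3 at 0.0564 against 8.20 CPM. Without GF small intestinal non-neuronal replicate 3 the log2 fold change of Arc went from -8.11 to 1.77. That library had the highest mean log2(CPM + 1) of its group in immediate early genes (6.32 against 4.39 and 4.91), pancreatic acinar markers (2.63 against 0.62 and 0.22) and epithelial markers (5.28 against 2.55 and 3.52). Mitochondrially encoded genes had a median of -1.59 (0 of 13 called, 9 lower adjusted over the list alone, camera adjusted p = 1.03e-07; adjusted p = 0.79 with an estimated correlation). Leaving out GF small intestinal non-neuronal replicates 1, 2 and 3 gave 2, 38 and 0 called genes, and leaving out SPF replicates 1, 3 and 4 gave 0 each.

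Xist counts set 8 of the 28 libraries apart, all of them SPF, while no label gives the sex of the animals. Differences between SPF and GF and a difference in sex may therefore be partly confounded. With the SPF libraries on the GF side of this split alone, Ahr in colonic neurons had a log2 fold change of 1.69 (SE 0.69).

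Interaction tests asked whether the segment, fraction or microbiota effects differ from each other. The SPF to GF change differed between colonic and small intestinal neurons for 0 genes by edgeR (1070 at an unadjusted p below 0.05, DESeq2 24, limma-voom 0), and between neuronal and non-neuronal colonic nuclei for 0 genes (1413 at an unadjusted p below 0.05, DESeq2 142, limma-voom 1). The lowest p in the first were for Mxra8, Cited2, Pou3f3, Hif3a and Rasgef1b, and in the second for Bcl2l1, Dab2, Pdgfra, Synm and Creg1. The segment difference in SPF animals, as the log2 fold change of colon over small intestine, differed between the fractions for 187 genes. It was higher in neuronal than in non-neuronal nuclei for 22 and lower for 165. Among the 22 were Grm8, Hcn4, Sctr and Pde1c, and among the 165 was Cdh9, which was absent from SPF colonic neuronal libraries. The interstitial cell list had a median difference of -8.16 (2 of 5 called, 4 adjusted over the list alone, camera adjusted p = 1.03e-08) and the neurotransmitter receptor list -3.16 (5 of 22 called, 13 adjusted over the list alone, camera adjusted p = 2.32e-09). Over all genes the median difference was -0.35. Without SPF small intestinal non-neuronal replicate 1, 484 genes were called, and without SPF colonic neuronal replicates 2 and 3, 123 and 107 were.

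Genes that differed by segment were compared with those that differed by microbiota in colonic neurons, since both use the same 4 SPF colonic libraries. With edgeR, 0 genes were called in both. With DESeq2, 4 genes were higher in both comparisons (0.858 expected for independent lists) and 10 lower in both (0.733 expected), and 2 were called in opposite directions. Simulated unchanged groups that shared libraries gave at most 2 and 3 shared calls with DESeq2, but from much shorter lists. In the data, 165 genes were higher and 264 lower by segment, and 90 higher and 48 lower by microbiota. No simulation gave more than 18, 13, 22 and 16 in the same order. The simulations therefore do not measure the overlap that shared libraries give between lists of the observed length. When the 4 shared libraries were split between the comparisons, DESeq2 gave 0 to 1 shared higher and 2 to 5 shared lower genes, and 3 to 8 called in opposite directions. Amigo1 and Nek3 were among the 4, and Lgr5, Mxra8, Akr1b3, Yap1 and Rgma among the 10.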

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

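Most tests in this part were chosen after the result was seen: the carry-over, tissue share, smooth muscle share, neuronal share and non-neuronal RNA tests were, and the direction of the neuron lists in colonic non-neuronal libraries was known before the test of neuronal nuclei there was run, while the test of further interstitial cell genes was set down before its result. The test with SPF replicates 1 and 2 only was added after Xist had been seen, before its value for Ahr was known.

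Of 84 sets of 4 libraries examined, 8 held a library whose gap to its neighbour exceeded Dixon's critical share of the range, where chance gives about 1 in 20, or 4.2. SPF small intestinal neuronal replicate 2 had 15661 genes with 10 or more counts, against at most 13991 in the others. In SPF colonic neuronal replicate 4 the most abundant gene took 3.28% of counts, against at most 2.68%. SPF small intestinal non-neuronal replicate 1 stood apart in the mean log2(CPM + 1) of the pan-enteric neuron markers, at 4.22 against at most 1.80 in the others, and was the highest of its group in the cholinergic genes, at 4.76. SPF small intestinal neuronal replicate 4 had the lowest pan-enteric neuron level of its group, at 7.13. SPF colonic non-neuronal replicate 2 had the lowest fibroblast level, at 5.74. SPF colonic neuronal replicate 2 had the highest epithelial level, at 0.98. SPF small intestinal non-neuronal replicate 3 had a pancreatic acinar level of 0.72, against 0 in the others.

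The segment difference in SPF animals differed between neuronal and non-neuronal nuclei for 187 genes by an edgeR interaction test. Of 40 splits of the libraries, the real one and others drawn at random, only the real one reached that number. The highest other split gave 143, and the structure of the libraries behind that count was not resolved. These splits shuffle the segments within each fraction and so also remove the segment differences themselves. They therefore cannot decide whether chance accounts for the interaction. Positive differences mark genes whose log2 fold change of colon over small intestine was higher in neuronal than in non-neuronal nuclei. They were seen for the pseudogene Ptges3-ps (12.80), Grm8 (9.70), Hcn4 (8.65), Sctr (5.73), Dgkq (5.70), Lurap1 (4.95), Tmem65 (4.45), Pde1c (4.32), Rab11fip2 (3.84) and Tm6sf1 (3.79). A positive difference need not mean a higher level in colonic neurons. In SPF non-neuronal libraries Grm8, Hcn4, Sctr and Tm6sf1 were lower in the colon, with log2 fold changes of -6.89, -9.05, -9.08 and -3.95. Negative differences were seen for Ackr2 (-14.49), Cdh9 (-13.61), Pkhd1 (-13.56), Cbs (-12.96), Smad7 (-12.70), the pseudogene Rpl23a-ps14 (-12.47), Sla (-11.18), Neurl1b (-10.97) and Nlrc4 (-10.73). The largest of these fitted differences involve groups without counts and depend on the prior count of the fit. Dgkq overlaps Idua and Tmem175, Lurap1 overlaps Pomgnt1, Tm6sf1 overlaps Hdgfl3 and Rpl23a-ps14 lies within Cep112, so reads of these genes can be shared.

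Gene lists whose median segment difference differed between fractions in SPF animals were the interstitial cell list (-8.16), endothelial markers (-3.59), neurotransmitter receptors (-3.16), sodium channels (-2.82), synaptic vesicle genes (-2.62), pan-enteric neuron markers (-2.49), cholinergic genes (-1.78), mitochondrially encoded genes (-1.30), nuclear-retained RNA genes (-1.28), cholesterol synthesis genes (-1.24) and fibroblast markers (1.31). With an estimated correlation, the camera calls of the interstitial cell list (adjusted p = 0.00707) and the receptor list (adjusted p = 0.00676) held and the other 9 did not. The SPF to GF difference in the colon differed between fractions for the intrinsic primary afferent neuron list (median 4.88), immediate early genes (1.71) and fibroblast markers (1.52), with adjusted p of 0.534, 0.659 and 0.212 with an estimated correlation.

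Interstitial cell of Cajal genes stood as high in SPF small intestinal neuronal libraries as in non-neuronal ones, with Ano1 at 247 and Kit at 243 CPM, although the 5 members ran from -5.14 to 3.79 and, without SPF small intestinal neuronal replicate 1, Ano1 and Kit turned from 0.44 and 0.47 to -0.83 and -0.39. General carry-over of non-neuronal RNA is argued against, since the interstitial cell list lay 5.30 above the smooth muscle and fibroblast lists (medians 0.47 and -4.82, exact two-sided permutation p = 0.00682 over 5 and 19 genes, which are not independent replicates), and 4.89 to 6.40 above them with any 1 library left out, 4.89 without that replicate. A larger number of these cells in the small intestine is argued against as the whole account, since the non-neuronal fraction showed a median segment difference of -0.748 for the list and no member below -1.86, against at most -3.39 in neuronal libraries. Interstitial cell nuclei inside the small intestinal neuronal gate remain a candidate explanation: 5 further genes of these cells, listed before the test, had a median of -1.23 in the neuronal segment comparison, with Slc12a2 at -1.23, Lrig1 at -2.18 and Pde3a at -1.40 but Elovl7 at 0.57 and Slc4a4 at 0.11, and 0 of them called. The sort for the fluorescent envelope protein would remove cells in which the CaMKII promoter is silent, and activity of the promoter in these cells, or the genes' own expression in small intestinal neurons, was not tested.

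Neuronal transcripts were higher in colonic than in small intestinal non-neuronal libraries. A lower smooth muscle share that raises all other cell types alike is argued against, since the neuron list lay 2.96 above the fibroblast list in the SPF comparison (exact two-sided permutation p = 0.00485 across genes). Neuronal nuclei or RNA in the colonic non-fluorescent sort, for instance from neurons the virus did not reach, are a candidate explanation: of 1052 genes higher in GF small intestinal neurons, 85.8% had a positive segment difference in SPF non-neuronal libraries against 48.4% of 17215 other genes. The opposite pairing of libraries gave 74.8% of 1536 genes. A difference between the segments in how neurons and other cells are sorted stays open and untested.

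Ahr was higher in each SPF than in each GF colonic neuronal library. A difference in the sex of the animals is argued against as the whole cause, since with SPF replicates 1 and 2 only, which Xist did not set apart from GF, the log2 fold change was 1.69 (SE 0.69), and with a term for the libraries that Xist set apart it was 2.69 (SE 0.80). These lie on either side of 1.96, so a part from that source is neither shown nor excluded. A lower neuronal share in the GF sort is argued against by the pan-enteric neuron list, with a median of -0.182 and members from -0.66 to 0.80, all below the change of Ahr. RNA of non-neuronal cells is argued against because the lowest SPF colonic neuronal library held 1.41 times the Ahr level of the highest SPF colonic non-neuronal library. A response of Ahr to the microbiota remains a hypothesis that was found and tested on the same libraries, and its adjusted p over all genes was 0.411.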

How the results depend on the processing

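The alternatives with SPF replicates 1 and 2 only, with a term for the libraries that Xist set apart, and with a block for the microbiota interactions were chosen after seeing the data, and all others before the data were examined. RLE size factors and a mean of at least 2 CPM kept each count of called genes within 1.5 times its value. Among single genes, 2703 of the 3328 values of called genes kept their direction and call, 625 kept the direction but not the call and 0 reversed. Of 913 values of genes not called, 852 stayed so, 57 were called and 4 reversed: between the fractions of the SPF small intestine, Ano1 (0.44) had -0.24 with limma-voom and ranged from -0.83, without SPF small intestinal neuronal replicate 1, to 1.29 when single libraries were left out, and Kit -0.39 without the same library, and between SPF and GF small intestinal non-neuronal libraries Arc (-8.11) ranged from -9.886, without SPF replicate 1, to 1.77, without GF replicate 3. Except where fewer libraries or genes in a fit account for a lower count, the cause was not tested.

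DESeq2 called 2956 and 3742 genes between the fractions of the GF colon and small intestine. Between colon and small intestine it called 429 in SPF and 355 in GF neuronal libraries, and 1083 in SPF and 543 in GF non-neuronal libraries. Between SPF and GF it called 138, 10, 5 and 374 in colonic neuronal, small intestinal neuronal, colonic non-neuronal and small intestinal non-neuronal libraries. Its interactions gave 24 (microbiota by segment), 142 (microbiota by fraction) and 810 (segment by fraction), and 14 genes were shared by the segment and microbiota comparisons of neurons. Limma-voom called 3881, 3153 and 3526 between fractions of the SPF colon, GF colon and GF small intestine, 186 between SPF neuronal segments, 232 between GF non-neuronal segments, 1 between SPF and GF colonic neurons, 0 in small intestinal non-neuronal libraries and 1 for microbiota by fraction. With no low-count filter the neuronal segments gave 298 (SPF) and 173 (GF), the non-neuronal segments 579 and 303, SPF against GF 80 in colonic neurons, 1 in small intestinal neurons and 161 in small intestinal non-neuronal libraries, and the interactions 22, 30 and 630. With only the compared groups in the fit, GF segments gave 28 (neuronal) and 76 (non-neuronal) and SPF against GF small intestinal non-neuronal libraries 0. With all 28 libraries in the fit these were 33, 309 and 34, and the SPF non-neuronal segments gave 811. With SPF replicates 1 and 2 only, and so fewer libraries, fractions gave 420 (colon) and 1055 (small intestine), SPF segments 20 (neuronal) and 40 (non-neuronal), segment by fraction 16, and SPF against GF 1, 1 and 0 in colonic neuronal, colonic non-neuronal and small intestinal non-neuronal libraries. The term for Xist gave 0 in the last of these.

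A replicate block by library number gave 317 genes between colon and small intestine in SPF and 207 in GF non-neuronal libraries. Between SPF and GF it gave 2 in colonic neurons and 0 in small intestinal non-neuronal libraries. Libraries that share a number correlated at -0.071 to 0.104 across 7975 genes after group means were removed, and the main fits do not pair libraries by number. As hints that the numbers may mark animals or their cohorts, 14 of 28 libraries correlated best with a library of their own number (8.10 on average with shuffled numbers, permutation p = 0.049, tested after the data were seen), and Xist set the same 2 numbers apart in each of the 4 SPF groups.

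Leaving out each library in turn gave 773 to 1182 genes between the fractions of the GF colon and 1454 to 2173 in the GF small intestine. Between colon and small intestine it gave 57 to 118 in SPF and 24 to 58 in GF neuronal libraries, and 79 to 292 in SPF and 44 to 163 in GF non-neuronal libraries. Between SPF and GF it gave 0 to 5, 0 to 1 and 0 to 38 in colonic neuronal, small intestinal neuronal and small intestinal non-neuronal libraries. For segment by fraction it gave 107 to 484. The extremes came without GF colonic neuronal replicates 2 (773) and 3 (5), GF small intestinal neuronal replicates 1 (1454) and 3 (24), SPF small intestinal neuronal replicates 4 (57) and 2 (1), SPF colonic non-neuronal replicate 2 (79), SPF small intestinal non-neuronal replicate 1 (292 and 484), GF colonic non-neuronal replicate 1 (44), GF small intestinal non-neuronal replicate 2 (38) and SPF colonic neuronal replicate 3 (107).

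Over all comparisons, camera made 147 calls of lists at its preset correlation and 81 with an estimated one. All alternatives listed before the data were examined were run. Depth limits calls of genes near the floor of 0.41 to 1.25 CPM, and a change in them was not detectable at this depth.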

Other observations

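Posterior Hox RNA in the colon lay mainly outside the neuronal nuclei. Of the 9 Hox genes of paralogue groups 9 to 13, 6 were lower in SPF colonic neuronal than non-neuronal libraries (8 adjusted over the list alone), with a median log2 fold change of -6.75, or -3.75 with absent genes at their bound (camera adjusted p = 8.06e-06). In the GF colon 7 were lower (9 adjusted over the list alone), with a median of -8.72, or -4.08 at the bound (camera adjusted p = 1.66e-06). Both calls held with an estimated correlation. Among neuronal gene groups, sodium channel genes had a median of 5.04 in the SPF small intestine, with 8 of 11 higher and 1 lower in neuronal libraries (9 and 1 adjusted over the list alone, camera adjusted p = 3.84e-09), and synaptic vesicle genes had 4.36, with 8 of 14 higher (8 adjusted over the list alone, camera adjusted p = 2.88e-09). In the SPF colon the same lists had medians of 1.74 and 1.65, with 3 and 4 higher (5 and 5 adjusted over the list alone, camera adjusted p = 0.00110 and 8.03e-06); the sodium channel call was lost there, with adjusted p = 0.0851 with an estimated correlation.

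Of other cell types, mesothelial markers were lower in neuronal libraries of the SPF small intestine, with 5 of 5 called (5 adjusted over the list alone, median -6.81, or -6.33 with absent genes at their bound, camera adjusted p = 1.95e-05). Enteric glia markers had 3 of 8 lower in the SPF colon (6 adjusted over the list alone, median -3.55, camera adjusted p = 3.37e-04) and 2 of 8 in the SPF small intestine (2 adjusted over the list alone, median -2.97, or -2.06 at the bound, camera adjusted p = 0.0245). Macrophage markers had 5 of 10 lower in the SPF colon (8 adjusted over the list alone, median -5.57, or -5.37 at the bound, camera adjusted p = 2.29e-05).

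Other splits of the libraries into groups of the same sizes were tested for each count of called genes. For the fractions of the SPF colon and small intestine, the real split was the 1 of 35 that gave as many genes (2270 and 3161), and the highest other gave 1. For the SPF segments, it was again 1 of 35, with 113 called genes in neuronal and 199 in non-neuronal libraries and 6 in the highest other for both. A share of 1 in 35 is the smallest these libraries allow and was not adjusted over the comparisons. It argues against chance in these SPF comparisons but does not exclude it. In the GF comparisons of fractions and segments, 3 against 3 libraries allow 10 splits, too few for a share under 0.05, and the real splits gave 1500, 2291, 52 and 130 genes with 0 in the highest other. For SPF against GF in colonic neuronal, small intestinal neuronal and colonic non-neuronal libraries, a count of 0 is reached by all 35 splits whatever the data (3, 1 and 0 in the highest other) and decides nothing. At an unadjusted p below 0.05, 12, 23 and 23 of the 35 splits gave at least the real 1599, 414 and 445 genes, with 1915, 622 and 748 in the highest other, so chance is not excluded. The single gene in small intestinal non-neuronal libraries was matched or exceeded by 11 of 35 splits, with 5 in the highest other, and chance is not excluded for it. The interactions of microbiota with segment and with fraction, with 0 genes, are likewise reached by 100 of 100 and 40 of 40 splits whatever the data (7 and 1 in the highest other). At an unadjusted p below 0.05, 30 of 100 and 13 of 40 gave at least the real 1070 and 1413 genes, with 1402 and 1640 in the highest other, and chance is not excluded.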
